A study of Mus musculus with 8 samples.

How the data were processed

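Total RNA of femoral growth plate cartilage from 8 littermate mice, 4 Cre and 4 CreTW at 12 days of age, was measured on 1-colour (Cy3) Agilent 8x60K mouse arrays from 100 ng of RNA per array, per the labels. The labels name 4 mice of each genotype, and each array was 1 replicate. The intensity values were made by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers, which subtract background from each spot's signal to give the processed intensity used here, and give the probes on the mm9 build. The authors worked on the values with GeneSpring 14.9, per the labels. The deposited log2 value table equalled the log2 of the processed intensity minus a constant per array (r = 1 on each of 8 arrays). That constant minus the log2 of the array's 75th percentile over non-control probes lay between -0.0056 and -0.0030. The table's genes were not centred, its medians lay between -3.03 and -2.93, and its direction needs no setting because each array holds 1 sample.

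The processed intensities of a probe's non-control spots were averaged, leaving out spots with outlier flags unless all spots of the probe were flagged. The averages were taken to log2, and the array's 75th percentile was subtracted. A probe was kept if it was well above background on at least 4 of 8 arrays. Probes were named through the RefSeq transcript table of another assembly (GRCm38.p6), used for names alone. Of 56605 probes, 32994 matched 1 symbol, 0 several and 23611 none, and a feature without a symbol kept the name in the files. For a gene with several probes the one with the highest mean was used. This left 23105 features, 14127 of them with a symbol. A changed gene with some arrays not well above background was also computed with those arrays raised to the array's lowest signal well above background. Where all arrays of a genotype were below background for every probe of a gene, the fold is a bound, the brighter genotype's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own.

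Genotypes were compared on all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 6 residual degrees of freedom and 2.52 prior ones. Before the data were examined, 33 gene lists were fixed, of which 31 had at least 3 measured members and were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether members move one way on balance (1 list called) or in either direction (8 called). By the symbols used here, the mitochondrial DNA list had 0 measured members and the sex-linked list 1. Features without a symbol were assigned to no list. The rule for named genes was also fixed then. It took Twnk, each measured gene of mitochondrial DNA (0 by the symbols used here), and Col2a1, Acan, Col10a1, Sox9 and Ihh. It also took the 10 largest rises and 10 largest falls among genes with an ordinary symbol that passed the test with separated groups (5 falls met this). From each list it took up to 4 changed members, or its 2 brightest where none changed. Apart from Twnk and Xist, members of lists that were neither main lists nor called nor held a changed gene are not named. Genes named outside the rule are said to be so.

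On simulated arrays of the same 23105 features, 5 runs with 200 changed genes each, 25.1% of genes changed by 0.5 on the log2 scale were recovered, 69.6% of those changed by 1 and 93.6% of those changed by 2, with 4.14% false among the calls. A list shifted by 0.3 was called in 5 of 5 runs, and 0 of 150 unshifted lists were. The simulated genes varied independently of one another. In the data the estimated correlation of members was, for example, 0.29 for the stress response list and 0.87 for skeletal muscle markers. The runs therefore do not show how often camera calls unshifted lists with correlated members.

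Alternatives fixed before the data were examined were the array median, quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, the replicate number as a block, the slide row as a block, eBayes with trend and robust, array weights and leaving out each array. Normexp was planned on the mean signal, which the files used here lack, and was run on the median signal. Xist as a covariate was planned for arrays that differ in sex. Xist was well above background on all 8 arrays (log2 -0.21 to 0.66), so this was not run. Probes of the other sex-linked genes were so on 0 arrays, except 1 probe that was so on 2 arrays (log2 -5.94 to -1.95). Added after seeing the data were the skeletal muscle score and the osteoclast score as covariates, CreTW replicate 1 alone against the 4 Cre arrays, features with a symbol alone, each slide row alone, and, for the stress response score, the perichondrium, tendon and fibroblast score. All 8 arrays lay on 1 slide and in 1 scan.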

Results

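RNA of femoral growth plate cartilage was measured in 12-day-old littermate mice of 2 genotypes, 4 labelled Cre and 4 labelled CreTW. The growth plate is the cartilage disc near the end of a long bone whose chondrocytes divide, enlarge and lay down the matrix along which the bone lengthens. The labels do not spell out the genotypes. As background on this study, the Cre animals express the recombinase in cartilage, and the CreTW animals express there in addition a mutant form of Twinkle, the helicase that replicates mitochondrial DNA. The series title names the question, which is what loss of the respiratory chain does to growth cartilage. Each RNA was hybridised alone to a 1-colour Agilent array. Between 45.4% and 57.9% of the 56605 probes were well above background on an array, no spot was saturated, and the array's 75th percentile signal lay between 144 and 187 scanner units. Arrays of the same genotype correlated at a mean r of 0.985 across the probes kept and arrays of different genotypes at 0.981. With 4 arrays per genotype, the number of arrays limits the precision. Fold changes below are CreTW over Cre with the SE of the log2 value, n = 4 arrays per genotype, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 23105 features.

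Genes that rose in CreTW cartilage included 13 of 38 measured genes of the integrated stress response and several that were not well above background in Cre cartilage. Trib3, a pseudokinase induced in the integrated stress response, rose 7.55-fold (log2 2.92 ± 0.17, adjusted p = 0.00078). Slc7a3, a cationic amino acid transporter, rose 7.85-fold (log2 2.97 ± 0.23, adjusted p = 0.00229), and Cdsn, an adhesion protein known from the epidermis, rose 16-fold (log2 4.0 ± 0.14, adjusted p = 2.18e-05). The structural genes of cartilage did not pass the test: Col2a1 had a log2 fold change of -0.05 ± 0.13 and Acan one of 0.01 ± 0.14. In all, 80 features changed at adjusted p 0.05, 53 higher and 27 lower in CreTW, and 49 of them by at least 2-fold (27 higher and 22 lower). The count was 42 to 75 without single arrays, 12 with the replicate number as a block and 4 with the skeletal muscle score as a covariate. Without adjustment, 2479 features had p under 0.05. The 4 CreTW values of each of the 80 lay all above or all below the 4 Cre values, as did 6.70% of all features tested, against 2.86% expected by chance. The 80 were chosen by a test on these same values, so their separation adds no support to the calls.

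The largest rises by the rule for named genes were of several kinds. Cox6a2, the heart and skeletal muscle form of a complex IV subunit, rose 21.9-fold (log2 4.45 ± 0.63, adjusted p = 0.0271), with 3 of 4 Cre arrays above background. Ccl21a, a chemokine, was well above background on 1 of 4 Cre arrays and rose at least 7.33-fold (adjusted p = 0.0272), with the other 3 raised to the lowest signal well above background on their array, a calculation added after the values were seen. Ccl21a has near-identical gene copies, so its probe may not tell them apart and the value is uncertain for a single gene. B4galnt2, a glycosyltransferase, Car6, a secreted carbonic anhydrase, and Cyb5r2, a cytochrome b5 reductase, were not well above background on any Cre array and were so on all 4 CreTW arrays. Their rises were therefore bounds, at least 8.49-fold for B4galnt2 (adjusted p = 0.00229), at least 4.42-fold for Car6 (adjusted p = 0.0162) and at least 5.88-fold for Cyb5r2 (adjusted p = 0.00229). For these genes and Ccl21a the adjusted p-values come from the limma fit on the values as measured and do not test the bounds. The bounds hold for the main processing. Over the alternatives the lowest log2 differences were 1.455 for B4galnt2, 0.86 for Car6, 1.08 for Cyb5r2 and 1.42 for Ccl21a, below these bounds. Gdf15, a secreted stress cytokine, rose 6.04-fold (log2 2.60 ± 0.36, adjusted p = 0.0258), or 5.35-fold with the 1 Cre array that was not well above background raised likewise, and Chac1, an enzyme that degrades glutathione, rose 3.81-fold (log2 1.93 ± 0.20, adjusted p = 0.00633). Markers of skeletal muscle were also higher on 3 of the CreTW arrays than on any Cre array (scores under the account of cell types below), and with their score in the fit the log2 difference of Cox6a2 was 2.54 (adjusted p = 0.152). In that fit 23 of 27 named calls were lost, so the loss of the call is not particular to Cox6a2. Among those lost were Slc7a3 (2.94, adjusted p = 0.0907), Chac1 (2.10, 0.137), Gdf15 (2.69, 0.454), Car6 (3.92, 0.137) and Ccl21a (2.88, 0.675). The log2 differences of Cox6a2 and Ccl21a became smaller (from 4.45 and 3.77), and that of Slc7a3 changed little (from 2.97). Those of Chac1, Gdf15 and Car6 became larger (from 1.93, 2.60 and 3.27). The calls of Cox6a2, Ccl21a, Car6 and Gdf15 were lost without some single arrays (highest adjusted p 0.107, 0.107, 0.0714 and 0.0819). The calls of the other 6 were kept without each array in turn.

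Few genes with a symbol were lower. Pde5a, a cyclic GMP phosphodiesterase, was 2.16-fold lower (log2 -1.11 ± 0.12, adjusted p = 0.00762) and was called without each array in turn. H2-Ab1, a class II major histocompatibility chain, was 2.15-fold lower (log2 -1.10 ± 0.16, adjusted p = 0.0309), with values of -0.97 to -1.12 on its 4 probes. Adcyap1r1, the receptor of the neuropeptide PACAP, was 2.14-fold lower (log2 -1.09 ± 0.13, adjusted p = 0.0108), with 3 of 4 CreTW arrays above background. Grtp1 (log2 -0.69 ± 0.09, or -0.49 with the 2 CreTW arrays not well above background raised to that lowest signal) and Rspo3, a secreted enhancer of Wnt signalling (log2 -0.64 ± 0.09), completed the 5 that met the rule. The sixth gene with a symbol that fell, 2610528A11Rik, lies outside the rule by its name and was chosen after its value was seen, with a log2 fold change of -2.99 ± 0.44 (7.95-fold lower, adjusted p = 0.0315, 3 of 4 CreTW arrays above background). Without single arrays the calls of H2-Ab1, Adcyap1r1, Grtp1, Rspo3 and 2610528A11Rik were lost in at least 1 of 8 fits, with highest adjusted p-values of 0.103, 0.0536, 0.102, 0.108 and 0.108.

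Genes of the integrated stress response and targets of its transcription factor ATF4 rose. Skeletal muscle markers had a larger median log2 (3.16), but the stress response list had the lowest adjusted p of the 31 by camera and by fry in 1 direction. Of 38 measured members, 13 rose over all genes tested and none fell, and 24 rose when adjusted over the list alone. Over all genes, 8 to 11 rose without single arrays, 5 without the filter on dim probes, 2 with the replicate number as a block and 1 with the muscle score as a covariate. Fold changes were positive for 36 of the 38, with a median log2 of 0.49 (camera adjusted p = 3.27e-31, fry adjusted p = 0.00256, and adjusted p = 0.197 with an estimated correlation). Besides Trib3, Slc7a3, Chac1 and Gdf15, the transcription factor Atf5 rose 2.37-fold (log2 1.24 ± 0.11, adjusted p = 0.0035) and Ddit3, which encodes CHOP, 2.03-fold (log2 1.02 ± 0.09, adjusted p = 0.00344). The other 7 members were named after their values were seen. They were Asns, which makes asparagine (2.40-fold), all 3 listed enzymes of serine synthesis, Phgdh (1.82-fold), Psat1 (1.73-fold) and Psph (1.86-fold), the mitochondrial folate enzyme Mthfd2 (1.65-fold), the mitochondrial carboxykinase Pck2 (1.86-fold) and Eif4ebp1, a repressor of translation (1.60-fold). The calls of Psat1, Mthfd2, Pck2 and Eif4ebp1 were lost without some single arrays (highest adjusted p 0.0903, 0.116, 0.0714 and 0.159), those of Ddit3, Atf5, Asns, Phgdh and Psph without none. Atf4, also chosen after its value was seen, had a log2 fold change of 0.27 ± 0.10 (adjusted p = 0.368). The list score, the mean centred log2 value of the members, lay between -0.53 and -0.23 on the Cre arrays and between 0.32 and 0.47 on the CreTW arrays. Its exact permutation p was 0.0286 (two-sided), the smallest 8 arrays allow, and 0.295 adjusted over 31 lists. The scores of endoplasmic reticulum chaperones and of perichondrium, tendon and fibroblast markers had the same exact p-values. Arrays lay in 2 rows of 1 slide, each with 2 of either genotype, and the list median was 0.49 within row 1, 0.46 within row 2 and 0.49 with the row as a block.

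**Figure D1:**
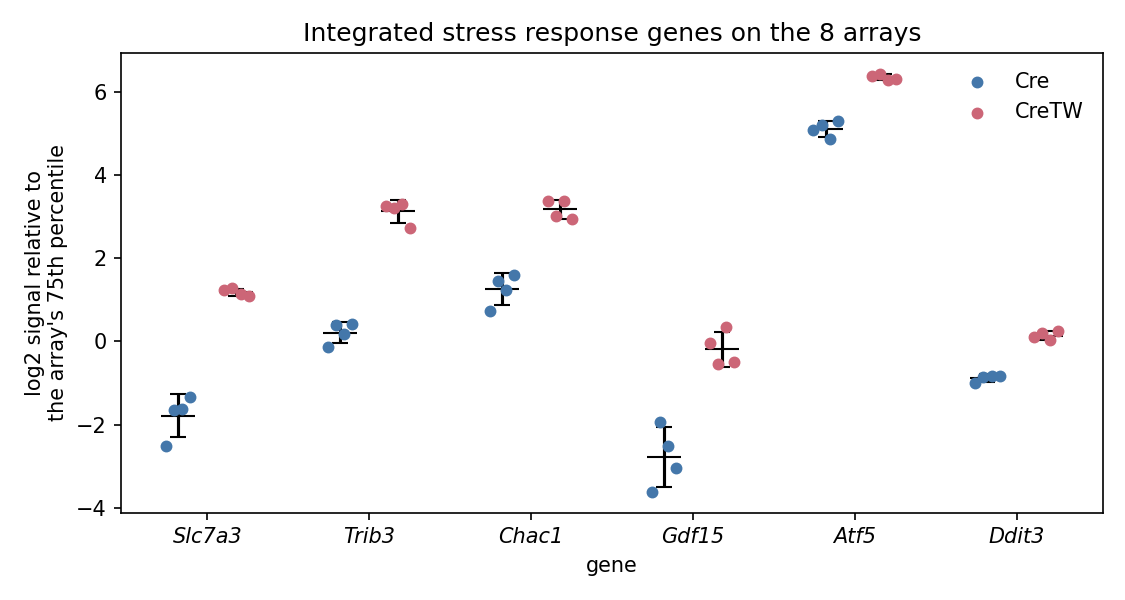
Log2 signal relative to the array's 75th percentile (vertical axis) for 6 stress response genes (horizontal axis), 1 point per array, Cre in blue and CreTW in red, with the mean (long dash) and SD (bars) of 4 arrays. For each gene all 4 CreTW values lie above all 4 Cre values, Slc7a3 and Trib3 by the widest margins. Levels of different genes come from different probes and are not comparable.

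No member of the fixed lists of nuclear respiratory chain genes passed the test, while Cox6a2, which is in neither, rose. None of 36 complex I subunits changed (median log2 0.02, camera adjusted p = 0.592), with Ndufa13 at 0.12 ± 0.08 and Ndufa2 at 0.12 ± 0.08, and none of 40 subunits of complexes II to V (median -0.01, camera adjusted p = 0.526), with Cox6a1 at -0.09 ± 0.09 and Cox8a at 0.05 ± 0.09. With the muscle score in the fit complex I subunits passed (median 0.11, adjusted p = 0.00859), and complexes II to V passed within slide row 1 (-0.12, adjusted p = 0.0201) but not within row 2 (0.06, adjusted p = 0.127). Genes of mitochondrial DNA maintenance and transcription had 0 of 25 changed (camera adjusted p = 0.708). Twnk, the gene of Twinkle, was at -0.10 ± 0.21 (adjusted p = 0.89), and since it is not known whether its probe reads the transgene, this checks no label. The mitochondrial ribosome had 0 of 74 changed (median -0.03, camera adjusted p = 0.259), the tricarboxylic acid cycle 0 of 29 (median -0.03, adjusted p = 0.798) and fatty acid oxidation 0 of 21 (median 0.02, adjusted p = 0.96). Among 21 mitochondrial chaperones and proteases 1 rose, Hspa9, the mitochondrial HSP70, (log2 0.59 ± 0.08, adjusted p = 0.0258), a call lost without any 1 of the 8 arrays (highest adjusted p 0.108). That list was not called in 1 direction by camera (adjusted p = 0.526), whereas fry for change in either direction gave it the lowest adjusted p of the lists, 2.27e-05. Fry in either direction also called the stress response (5.99e-05), endoplasmic reticulum chaperones (7.1e-05), fibroblast markers (0.00945), matrix proteases (0.0161), antioxidant genes (0.0279), genes near Gt(ROSA)26Sor (0.0279) and HIF targets (0.0432), as adjusted p-values. By the symbols used here the list of genes encoded in mitochondrial DNA had 0 measured members, so it was not analysed here. The 8978 features without a symbol were assigned to no list, and whether transcripts of mitochondrial DNA are among them is left open. A run of 10 such features, all with negative fold changes, is described under other observations.

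Glycolysis genes were shifted lower in CreTW by camera at its preset correlation. None of the 24 members passed over all genes tested, 20 had negative fold changes, and the median was -0.31 (camera adjusted p = 3.73e-05, but adjusted p = 0.694 with an estimated correlation). Adjusted over the list alone, 3 members were lower and 1 higher, of which Slc16a3, Pfkfb3 and Eno2 were named after their values were seen. Ldha, lactate dehydrogenase, was at -0.47 ± 0.14, the lactate exporter Slc16a3 at -1.45 ± 0.33, the regulator Pfkfb3 at -0.57 ± 0.16, and the enolase Eno2 at 0.75 ± 0.19. Pgk1, another of the brightest members, was at -0.55 ± 0.18. The mean score differed by -0.28 ± 0.14 (SE), by -0.45 ± 0.12 with the osteoclast score in the model and by -0.19 ± 0.23 with the muscle score, covariates chosen after the data were seen. Without covariates the exact permutation p of the glycolysis score was 0.143 (two-sided). Within slide row 1 the list median was -0.23 and within row 2 it was -0.33. HIF targets, many of which respond to low oxygen, had a median of -0.21 with 0 of 31 changed (camera adjusted p = 0.0186, and adjusted p = 0.858 with an estimated correlation). Over the list alone 1 was lower, named after its value was seen, Egln3, a HIF prolyl hydroxylase, at -0.83 ± 0.15. The brightest, Higd1a and Loxl2, were at -0.54 ± 0.21 and 0.17 ± 0.14. The call on HIF targets was lost without Cre replicate 4 (median -0.10, adjusted p = 0.224).

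No single gene of the cartilage lists passed over all genes tested, and 1 of these lists was called as a set. Of 35 cartilage matrix genes 0 changed. Their median was -0.08 and their mean 0.04, while camera gave an upward direction, so these differ in sign (camera adjusted p = 0.92). The median was 0.21 within slide row 1 and -0.38 within row 2, opposite directions that each passed (camera adjusted p = 0.000953 and 0.005). Without Cre replicate 4 the list also passed (median 0.08, adjusted p = 0.0438). Of 20 genes of hypertrophic chondrocytes, the enlarged cells next to bone, 0 changed (median -0.13, camera adjusted p = 0.405). Col10a1, the collagen of these cells, was at 0.20 ± 0.16, Spp1 at 0.07 ± 0.29, and Ihh, the hedgehog ligand that paces chondrocyte maturation, at -0.86 ± 0.41 (adjusted p = 0.503). Chondrocyte transcription factors and signalling genes had a small upward shift, with 0 of 33 changed and a median of 0.08 (camera adjusted p = 0.0427, and adjusted p = 0.954 with an estimated correlation). The call was lost without each of Cre replicates 1, 2 and 3 and CreTW replicates 1, 2 and 4 (medians 0.04 to 0.07), and the median was -0.12 within slide row 2 and -0.09 with the osteoclast score as a covariate. Sox9, which specifies chondrocytes, was at -0.29 ± 0.28, Sox5 at 0.10 ± 0.09 and Fgfr3 at -0.05 ± 0.24. Matrix proteases and inhibitors had 0 of 19 changed (camera adjusted p = 0.775). Over the list alone 2 were higher and 1 lower.

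Among other processes, proliferation genes were lower by a little, with 33 of 35 fold changes negative, 0 changed and a median of -0.23 (camera adjusted p = 1.3e-09, and adjusted p = 0.694 with an estimated correlation). The exact permutation p of their score was 0.114 (two-sided). Birc5 was at -0.33 ± 0.11 and the replication factor Mcm6 at -0.13 ± 0.09. Endoplasmic reticulum chaperones, which fold secreted proteins, had 18 of 22 fold changes negative, 0 changed and a median of -0.19 (camera adjusted p = 4.49e-05, and adjusted p = 0.599 with an estimated correlation). Over the list alone Hsp90b1, named after its value was seen, was lower (-0.34 ± 0.08), and the brightest, Serpinh1, a collagen chaperone, and Pdia6, were at -0.28 ± 0.12 and -0.22 ± 0.09. Cholesterol synthesis genes had a median of -0.19 with 0 of 24 changed (camera adjusted p = 0.00567, and adjusted p = 0.954 with an estimated correlation), with Hmgcs1 at -0.16 ± 0.20 and Ebp at -0.24 ± 0.10. That call was lost without Cre replicate 4 (median -0.02) and without CreTW replicate 3 (median -0.09). Antioxidant genes (0 of 26), p53 targets (0 of 21), interferon-stimulated genes (0 of 21) and immediate early genes (0 of 17) had no member past the test and were not called in 1 direction (camera adjusted p = 0.526, 0.306, 0.75 and 0.526). Immediate early genes passed without CreTW replicate 1 (median -0.31, adjusted p = 0.000968).

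Of 9 lists of markers of other cell types, 5 were called by camera at its preset correlation and 0 with an estimated one. All 22 skeletal muscle markers had positive fold changes with a median log2 of 3.16 (2.44 to 4.43 without single arrays). None passed over all genes and 17 did over the list alone (camera adjusted p = 9.71e-16, and adjusted p = 0.599 with an estimated correlation). The brightest, Tnni2 and Tnnt3, were at 0.31 ± 0.44 and 1.46 ± 0.66. The muscle score was -1.94, -2.63, 0.23 and -2.04 on Cre replicates 1 to 4 and -1.16, 3.15, 2.63 and 1.75 on CreTW replicates 1 to 4 (exact permutation p = 0.0571, two-sided; 0.443 adjusted over 31 lists). Markers of perichondrium, tendon and fibroblasts had a median of 0.45 (camera adjusted p = 1.12e-11, and adjusted p = 0.599 with an estimated correlation), with 12 of 24 higher over the list alone and 1 over all genes, Thy1 (log2 0.60 ± 0.08, adjusted p = 0.0258), whose call was lost without 7 of the arrays taken singly (highest adjusted p 0.108). Osteoclast markers had negative fold changes for 15 of 15 (median -0.81, camera adjusted p = 4.54e-05, and adjusted p = 0.694 with an estimated correlation, exact permutation p of the score 0.2), with a median between -1.13 and -0.50 without single arrays but 0.17 within slide row 2, Acp5 being at -0.81 ± 0.47 and Ctsk at -0.62 ± 0.41. Erythroid markers did for 13 of 13 (median -0.62, camera adjusted p = 2.51e-05, and adjusted p = 0.599 with an estimated correlation), Hba-a1 and Hba-a2 being at -0.62 ± 0.29, and Rhd, the only one lower over the list alone and named after its value was seen, at -0.82 ± 0.20. The exact permutation p of the erythroid score was 0.0857 (two-sided). Osteoblast and osteocyte markers had a median of -0.28 (camera adjusted p = 0.046, and adjusted p = 0.858 with an estimated correlation), with Col1a1 at -0.05 ± 0.12, Col1a2 at -0.02 ± 0.12 and Pdpn, higher over the list alone and named after its value was seen, at 0.54 ± 0.10. That call was lost without any 1 array except Cre replicate 4 or CreTW replicate 3 (medians -0.26 to -0.15 in those fits). Neutrophil and monocyte markers (0 of 19 changed, camera adjusted p = 0.506), B lymphocyte markers (0 of 10, 0.174), endothelial markers (0 of 18, 0.212) and adipocyte markers (0 of 9, 0.322) were not called, but passed without Cre replicate 4 (medians -0.60, -0.65, -0.26 and -0.44), and B lymphocyte and endothelial markers also without CreTW replicate 3 (medians -0.52 and -0.26). Of 41 genes near the Gt(ROSA)26Sor locus, where transgenes are often placed, 0 changed (median -0.06, camera adjusted p = 0.306). The sex-linked list had 1 measured member, Xist, at 0.27 ± 0.18.

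**Figure D2:**
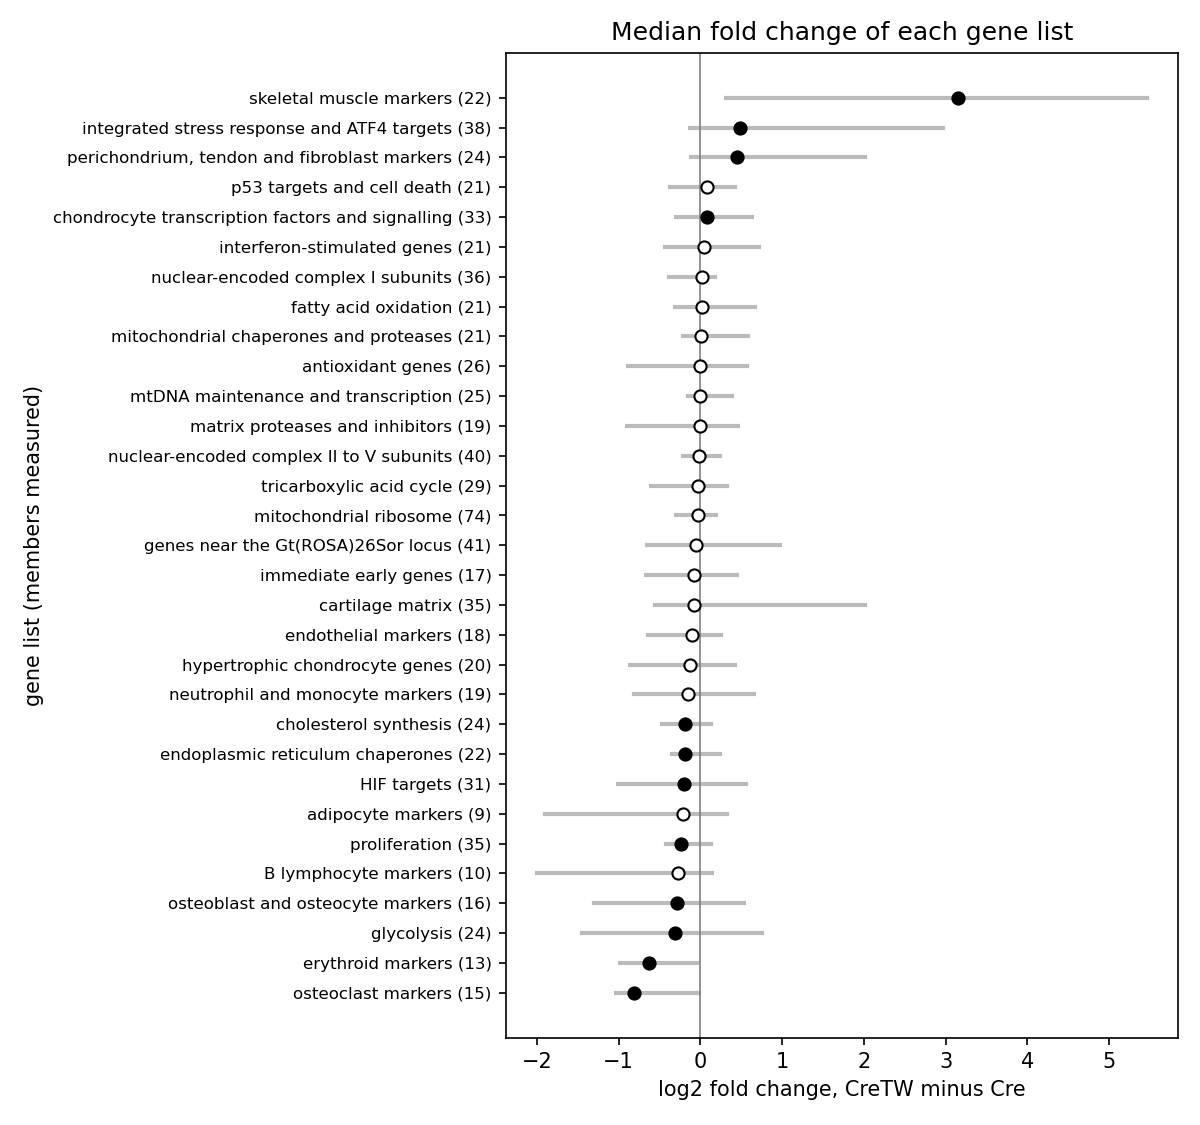
Median log2 fold change, CreTW minus Cre (point), and the range from the lowest to the highest member (grey line) of each of 31 gene lists, with the number of members measured in parentheses. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 passed with an estimated correlation. Skeletal muscle markers stand furthest to the right, at 3.16, and osteoclast markers furthest to the left, at -0.81.

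With the slide row as a block the fit called 53 features, and within row 1 or row 2 alone (2 against 2) it called 0 (limma, with 3164 and 1216 features at unadjusted p under 0.05). Of the 35 ways to part the 8 arrays into 4 and 4, 1 other gave more calls than the genotypes did, and 22, the genotypes included, gave at least as many gene lists as the 12 called by camera.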

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

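The tests weighed here with the muscle score, with the fibroblast score and on the shared component of the muscle markers were chosen after the results were seen. The osteoclast and erythroid tests were set down before their results.

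In 14 of 198 sets of 4 arrays of a genotype, 1 array stood apart from the other 3 by more than the critical Dixon ratio, against 9.9 expected by chance. Cre replicate 4 accounted for 7. Its score was 0.44 for cartilage matrix (others -0.21 to -0.12), 0.32 for chondrocyte transcription factors and signalling (others -0.22 to -0.14), -0.57 for osteoclast markers (others 0.60 to 0.75), -0.38 for endothelial markers (others 0.18 to 0.26) and -0.62 for interferon-stimulated genes (others 0.13 to 0.29). Its log2 level was 8.16 for Acp5 (others 9.49 to 9.71) and 6.61 for Ctsk (others 7.79 to 7.98). Cre replicate 1 was low for Ddit3 (-1.0, others -0.85 to -0.83) and Hsp90b1 (5.94, others 6.08 to 6.11), and Cre replicate 3 for Eif4ebp1 (3.71, others 3.90 to 3.93). CreTW replicate 4 was high for Pdpn (3.22, others 3.02 to 3.05) and low for Rhd (-0.68, others -0.22 to -0.17). CreTW replicate 3 was low in cholesterol synthesis (-0.38, others -0.01 to 0.03) and CreTW replicate 2 in antioxidant genes (-0.17, others 0.03 to 0.07).

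Skeletal muscle markers were higher in CreTW, by 3.19 in the mean score. Within genotypes 1 component held 92.7% of the variance of the 22 markers, as muscle tissue taken along with the cartilage in varying amounts would give, so carried-over muscle is a candidate source. Expression of muscle genes by cells of the growth plate itself was not tested. Of the largest rises, Cox6a2 is itself a muscle gene, and its log2 difference was 4.45 before and 2.54 after the muscle score entered the fit.

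The rise of the integrated stress response genes was set against such differences in cell content. The genotype difference of the list score was 0.75 ± 0.08 (SE). With the muscle score in the model it was 0.86 ± 0.11 and with the osteoclast score 0.69 ± 0.09. It was 0.87 ± 0.13 with the perichondrium, tendon and fibroblast score, which also parts the genotypes fully. Taken singly, none of these linear trends across the arrays took the difference away. Such fits cannot tell genotype apart from a cell content that coincides with it. The number of single genes called in the list still fell, from 13 to 1, with the muscle score in the fit. There the median SE of the 38 genes grew from 0.111 to 0.166, as the score is correlated with genotype (r = 0.75). Their median residual SD, as moderated by eBayes, went from 0.157 to 0.155, while Trib3 was at 2.92 before and 2.99 after. A response of the cartilage cells to the genotype stays as a hypothesis, found on the same data. The fits above weigh cell content and do not test for a response inside these cells.

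Proliferation genes had a score difference of -0.22 ± 0.08. It was -0.10 ± 0.05 with the osteoclast score and -0.090 ± 0.096 with the erythroid score in the model. Both values lie near the middle between no difference and the full one, so fewer bone and marrow cells in the CreTW samples and a lower rate of division in cartilage cannot be told apart with 8 arrays.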

How the results depend on the processing

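Chosen after the data were seen were the muscle and osteoclast covariates, CreTW replicate 1 alone, features with a symbol alone and the slide rows alone. The other alternatives were planned, except that normexp ran on the median signal. All 80 changed features kept their direction in each fit that tested them. The integrated stress response list stayed past the threshold in 25 of 26 alternatives, fry among them, with medians of 0.38 to 0.68, and lost the call with the estimated correlation. Across alternatives 1120 values of named genes kept direction and side of the threshold, 263 lost the call, 5 gained one and 28 changed sign, none of the last for a called gene. Of 27 named genes past the threshold, 12 kept it without each array in turn and 15 did not. Other scalings moved the median of all features by under 0.1. Where no cause is given below, the cause was not tested. Signal over background limits the dim features: CreTW replicate 2, with the fewest detected probes, had 45.4% well above background.

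The count of 80 changed features (53 higher, 27 lower, 49 by 2-fold) became 27 (16, 11 and 27) without the filter on dim probes, where 45616 features were tested. It became 127 with array weights (90 higher) and 53 with the slide row as a block (35 higher). Trend and robust gave 84 higher. With features that have a symbol alone, 7 were lower, as most falls lack one. The muscle covariate gave 4 (4 higher, 0 lower, 4 by 2-fold), the osteoclast covariate 43 (25 higher), and CreTW replicate 1 alone against 4 Cre arrays 1 (1, 0 and 1), on the assumption that the lone array varies like the others. Slide row 1 alone and row 2 alone gave 0 in each direction and 0 by 2-fold, with 2 arrays per genotype. Leaving out single arrays gave 42 to 75 changed and 23 to 55 higher, the lowest without CreTW replicate 4. The share of higher calls was 66.3% and lay between 65.8% and 71.8% under the other scalings and background correction.

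With the replicate block the fit called 12 features (9 higher, 3 lower, 12 by 2-fold), with fewer degrees of freedom. Same-numbered arrays had deviations correlated at -0.01, -0.10, 0.31 and -0.03, and 1 of 4 CreTW arrays correlated best with its own number. So few values cannot settle whether the numbers pair the samples. The labels do not say that a shared number marks a shared litter. Under the block B lymphocyte markers passed (median -0.27).

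Of the 12 lists called by camera, 0 stayed with an estimated correlation and 1 with fry. Lost with the estimate were the stress response (median 0.49), and with both were glycolysis (-0.31), chondrocyte signalling (0.076), HIF targets (-0.21), cholesterol synthesis (-0.19), endoplasmic reticulum chaperones (-0.19), proliferation (-0.23), osteoblast (-0.28), osteoclast (-0.81), erythroid (-0.62), muscle (3.16) and perichondrium markers (0.45). Chondrocyte signalling (0.076) and osteoblast markers also left the threshold with the 8-array filter (-0.26), the mean of probes (-0.28) and symbols alone (-0.28), and osteoblast markers with the array median (-0.29) and quantiles (-0.28). Array weights ended HIF targets (-0.18) and cholesterol synthesis (-0.074), and brought in neutrophil (-0.57), B lymphocyte (-0.55) and endothelial markers (-0.23). No filter brought in adipocyte markers (-0.25). Medians near 0 changed sign: with no filter, matrix proteases (0.0096), mitochondrial DNA maintenance (0.014) and antioxidant genes (-0.013). With array weights cartilage matrix (0.0058), fatty acid oxidation (-0.012) and interferon-stimulated genes (-0.012) did, with the 8-array filter matrix proteases (0.00079), and with the mean of probes mitochondrial DNA maintenance (0.022). With the array median, mitochondrial chaperones (-0.0022) and antioxidant genes (-0.011) did, with normexp mitochondrial chaperones (-4.04e-05), and with the authors' table antioxidant genes (-0.0012).

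Under the muscle covariate complex I subunits passed (0.11), HIF targets did not (-0.076), and complexes II to V (0.067), cartilage matrix (0.11) and cholesterol synthesis (0.083) changed sign. Under the osteoclast covariate cartilage matrix passed (-0.42), osteoblast markers did not (-0.015), and complexes II to V (0.011) and chondrocyte signalling (-0.090) changed sign. In slide row 1 alone complexes II to V passed (-0.12), HIF targets (-0.19) and cholesterol synthesis (-0.030) did not, complex I (-0.025) changed sign, and cartilage matrix changed sign and passed (0.21). In row 2 alone cartilage matrix passed (-0.38), and complexes II to V (0.059), hypertrophic genes (0.022), chondrocyte signalling (-0.12), osteoblast (0.031) and osteoclast markers (0.17) changed sign.

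Without single arrays, medians ranged from -0.014 to 0.048 for complex I, -0.047 to 0.016 for complexes II to V, -0.20 to 0.079 for cartilage matrix, 0.039 to 0.20 for chondrocyte signalling, -0.062 to 0.067 for matrix proteases, -0.25 to -0.10 for HIF targets, -0.026 to 0.042 for mitochondrial DNA maintenance, -0.011 to 0.033 for mitochondrial chaperones and -0.057 to 0.0014 for the tricarboxylic acid cycle. They ranged from -0.021 to 0.037 for fatty acid oxidation, -0.28 to -0.018 for cholesterol synthesis, -0.015 to 0.021 for antioxidant genes, -0.11 to 0.13 for interferon-stimulated genes, -0.31 to 0.11 for immediate early genes, -0.55 to -0.15 for osteoblast markers, -1.13 to -0.50 for osteoclast markers, -0.85 to -0.46 for erythroid markers, -0.60 to 0.19 for neutrophil markers, -0.65 to 0.021 for B lymphocyte markers, -0.26 to 0.017 for endothelial markers and -0.44 to -0.10 for adipocyte markers.

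Genes that had not passed also changed sign: Twnk (0.017 with array weights, -0.23 to 0.029 without single arrays), Col2a1 (0.043 with quantiles, -0.12 to 0.046), Acan (-0.0030 with the array median, -0.030 with quantiles, -0.081 to 0.13), Spp1 (-0.011 with quantiles, -0.054 with array weights, -0.17 to 0.24), Fgfr3 (0.027 with array weights, -0.21 to 0.16), Cox8a (-0.034 with quantiles), Sox5 (-0.055 with the mean of probes), Col1a1 (-0.13 to 0.0082), Col1a2 (-0.090 to 0.029) and Tnni2 (-0.0052 to 0.63).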

Other observations

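The counts of the other groupings were first seen for all changed features, so that test was chosen after the result, and those of 2-fold changes and of lists were set down before.

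Features without a symbol made up most of the falls, 21 of 27, against 6 of 53 rises. Of these, 15 fallen features bore Ensembl transcript names, and they were not spread evenly over the numbers. In a run of 30 consecutive transcript numbers, 10 features were measured, all 10 had negative fold changes, and 8 changed. With the features of this run left out, no run of 30 held more than 1 changed feature. The run with 8 was chosen after the values were seen. Its fold changes lay between -1.41 and -0.43 with a median of -1.21, for instance -1.38 ± 0.16 for ENSMUST00000082392 (2.60-fold lower, adjusted p = 0.00884) and -1.21 ± 0.11 for ENSMUST00000082421 (2.31-fold lower, adjusted p = 0.00351). These are bright features, with a mean log2 level of 6.62 in Cre and 5.48 in CreTW. The mean centred value of the 10 lay between 0.46 and 0.68 on the Cre arrays and between -0.71 and -0.29 on the CreTW arrays. The files used here do not pair these identifiers with gene names, and whether they belong to the mitochondrial DNA list is left open.

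The largest fall of all was a feature named in the files by its interval on mm9 chromosome 5, from 35975265 to 35982561, with a log2 level of 3.89 ± 0.64 (SD, n = 4) in Cre and 0.04 ± 0.15 in CreTW, 14.5-fold lower by limma (adjusted p = 0.00229). A further interval, on chromosome 4 from 141527564 to 141547339, fell by 1.58 on the log2 scale (adjusted p = 0.0035 by limma). Both were singled out after their values were seen, and which gene, if any, each reads is not given in the sources used here.

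Chance could not be excluded for the counts. Of 35 splits of the arrays into 4 and 4, 2 gave at least 80 changed features, the genotypes and a split of Cre replicates 1, 2 and 3 with CreTW replicate 3 from the rest, which gave 524. The same 2 gave at least 49 features changed by 2-fold or more, the other split 127. For gene lists called by camera, 22 splits gave at least 12 and the highest other split 18. A split that calls several times more points to a structure of the samples. The osteoclast score was 0.65, 0.75, 0.60 and 0.32 on the 4 arrays of its one side and -0.57, -0.51, -1.16 and -0.07 on Cre replicate 4 and CreTW replicates 1, 2 and 4. With that score as a covariate, a choice made after seeing the data, the genotype fit called 43 features, 37 of them among the 80, and the cartilage matrix median became -0.42 (camera adjusted p = 2.75e-05). Over its alternatives that list's adjusted p ranged up to 0.984.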
